A study of Mus musculus with 16 samples.

How the data were processed

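RNA of mouse primary hepatocytes was sequenced from stranded total RNA libraries in 16 samples: FLOX and HKO cells, each with vehicle or 0.4 mM palmitic acid for 24 h, 4 samples per group. The deposited values were TPM, made by the authors and given with 2 decimals for 55416 mouse Ensembl gene IDs. The submitters' notes list RSEM 1.3.3 and a human genome build, which cannot be the build of mouse IDs, so no coordinates are given. The aligner and the annotation release are not given in the sources used here. TPM keeps no depth, so the depth of each sample is unknown and no counting intervals were made.

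Symbols were taken from a gene-name table, which matched 52083 of the 55416 IDs (94.0%) and 11803 of the 11858 genes tested. Genes with a TPM of at least 1 in at least 4 of the 16 samples were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3. All 16 samples entered 1 fit with a mean per group and a mean-variance trend. The 5 comparisons were palmitic acid against vehicle in each genotype, HKO against FLOX under each treatment, and the interaction, which is the response of HKO minus that of FLOX. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was an adjusted p of 0.05. No batch, animal or culture is stated, so none was modelled. The sample titles number vehicle and palmitic acid samples of a genotype alike, which the main fit did not use. An alternative, the replicate block, took these numbers into account.

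A total of 26 gene lists with 421 genes were written before the data were examined, as were the tests, the threshold, the rule for naming genes and most alternatives. The lists were sphingomyelin turnover, ceramide metabolism, fatty acid oxidation, lipogenesis, cholesterol biosynthesis, lipid droplet, fatty acid uptake, unfolded protein response, inflammatory, acute phase, interferon, NRF2, p53 and apoptosis, extracellular vesicle biogenesis, caveolae, bile acid, glucose, cell cycle and mitochondrially encoded genes, and markers of hepatocytes, macrophages, endothelial cells, stellate cells, cholangiocytes, lymphocytes and neutrophils, and erythroid cells. Lists with at least 3 tested members were tested with camera from limma at a preset correlation of 0.01, and again with a correlation estimated per list. A further 7 lists (hypoxia, heat shock, pericentral, periportal, complement and coagulation, actin and SRF, proteasome) were chosen after the main results were seen and before their own tests. Genes were named by rule: Smpd3, up to 8 per direction with the largest changes past the threshold and no overlap between groups, and up to 3 members per list. The text leaves out some of these, and names Hspa8 and Dnajb1, outside the rule, after their values were seen. Timp1, which the rule picks, was added to the text after its values were seen.

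Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-ratio scaling, quantile normalization, no mean-variance trend, only the 2 groups compared, the replicate block, sample quality weights and leaving out each of the 16 samples. Those added after the data were seen were protein-coding genes alone, a correction for transcript length and GC content, and leaving out both FLOX libraries numbered 1. Calls were also tested on simulated data, in which 200 genes were given a known change. A change of 0.5 on the log2 scale was recovered for 65% of them with palmitic acid in FLOX, 72.5% between genotypes under vehicle and 35.5% in the interaction. Of the calls in these runs 7.80%, 7.64% and 8.97% were false. A change of 0.3 was recovered for 22.5%, 26.5% and 1%. The noise was drawn for each gene on its own, so structure shared by genes was not simulated.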

Results

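Gene expression was measured by RNA sequencing in cultured primary hepatocytes, the main cells of the liver, isolated from mice. The cells carried no Cre recombinase under the albumin promoter (FLOX) or carried it (HKO), in a cross made to delete Smpd3 in hepatocytes. Smpd3 encodes a neutral sphingomyelinase, an enzyme of membranes that splits sphingomyelin into ceramide and phosphocholine. Cells of each genotype received vehicle or 0.4 mM palmitic acid, a saturated fatty acid used to model steatohepatitis in culture, and 4 groups of 4 samples resulted. The design asks what the loss of Smpd3 does to hepatocytes with and without this fatty acid.

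The values were transcript abundances as TPM, each transcript's share of all transcripts in its sample, for 55416 genes, of which 11231 to 11498 reached 1 TPM in a sample. TPM keeps no sequencing depth, so the depth is unknown, and the precision of each value is given by the spread of the 4 samples of its group. The labels do not say whether the replicates came from separate mice or cultures, so the p-values measure the spread between these samples, which may be technical. Across genes, which are not independent replicates, samples of 1 group correlated at r = 0.980 at the lowest and samples of different groups at r = 0.965 to 0.984. The first principal component (31.6% of the variance) separated palmitic acid from vehicle, and the next (11.6%) separated FLOX from HKO. FLOX vehicle replicate 1 and FLOX palmitic acid replicate 1 stood at the ends of PC3 (7.53%), with scores of 16.1 and -19.0. Of the 219 gene comparisons past the threshold among the named genes, 214 had no overlap between the 4 and 4 samples. The threshold selects for this, and the rule for naming the largest changes requires it. The count is therefore not set against the 2.86% that chance gives for genes not selected. The 5 with overlap were Abcb4, Slc2a2 and Tlr2 between genotypes under palmitic acid, Cav2 with palmitic acid in FLOX and Stab2 with palmitic acid in HKO.

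Smpd3 (ENSMUSG00000031906) transcripts were low in every HKO sample. Their level was 32.0 ± 4.1 TPM in FLOX cells with vehicle and 5.29 ± 0.71 TPM in HKO cells with vehicle (mean ± SD, n = 4 each, as for all TPM values given here), and 46.0 ± 2.4 and 7.82 ± 1.1 TPM with palmitic acid. The HKO mean was 16.5% of the FLOX mean with vehicle and 17.0% with palmitic acid, with log2 fold changes of -2.39 ± 0.11 and -2.42 ± 0.11 (± SE, limma adjusted p = 7.87e-10 and 1.09e-09). Palmitic acid raised Smpd3 1.44-fold in FLOX cells and raised the remaining transcripts of HKO cells 1.48-fold, with log2 fold changes of 0.52 ± 0.11 and 0.49 ± 0.11 (limma adjusted p = 0.00138 and 0.00160). The percentages and folds are ratios of mean TPM, while the log2 fold changes are of TPM + 1, which makes them smaller at low levels. The difference between these responses was -0.030 ± 0.15 (limma adjusted p = 0.987). It kept its sign in 22 of 27 alternatives and ran from -0.14 to 0.049.

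**Figure D1:**
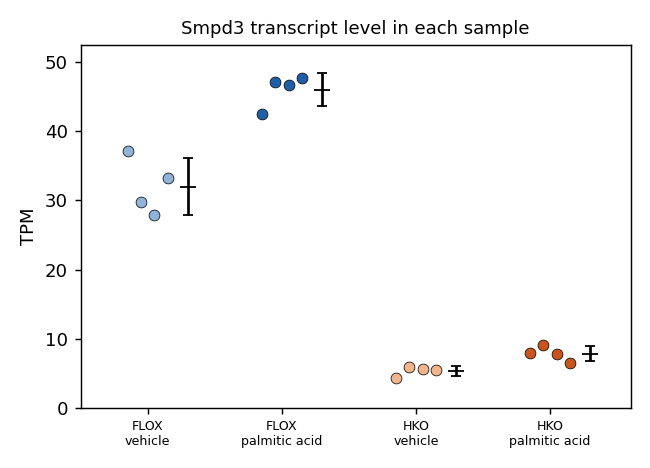
Smpd3 transcript level in TPM (y axis, linear) in each of the 4 samples of the 4 groups (points), with the mean and SD of each group. FLOX samples lie between 27.8 and 47.8 TPM and HKO samples between 4.25 and 9.15 TPM.

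Among the genes that palmitic acid raised in FLOX cells were some of lipid droplets and of fatty acid oxidation. Plin2, which coats lipid droplets, rose from 477 ± 22 to 2626 ± 224 TPM (log2 fold change 2.46 ± 0.057), and Cidec and Hilpda, other lipid droplet proteins, rose by 1.86 ± 0.070 and 2.22 ± 0.15. Pdk4, a kinase that restrains glucose oxidation, rose from 1.79 ± 0.23 to 32.0 ± 11 TPM. Angptl4, an inhibitor of lipoprotein lipase, and Creb3l3, a hepatic transcription factor, rose by 1.38 ± 0.052 and 1.62 ± 0.064. Of the list of fatty acid oxidation and PPARα target genes, 14 of 25 tested members (14 adjusted over the list alone) were higher and 3 lower, and the list was higher as a set (camera adjusted p = 0.00449, adjusted p = 0.235 with an estimated correlation). Lipid droplet genes went both ways: 8 of 16 were higher and 6 lower (8 and 6 adjusted over the list alone, camera adjusted p = 0.442). Fatty acid uptake genes did so too: 4 of 14 were higher and 5 lower (4 and 6 adjusted over the list alone, camera adjusted p = 0.242), with Fabp2, an intestinal-type fatty acid binding protein, at 0.92 ± 0.091 and the fatty acid receptor Cd36 at -0.89 ± 0.10.

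Genes of lipid synthesis fell. Cholesterol biosynthesis genes were lower for 17 of 22 tested members (17 adjusted over the list alone, camera adjusted p = 1.23e-14, adjusted p = 0.0497 with an estimated correlation). Their median log2 fold change was -0.41, and none was higher. Fdps, which makes farnesyl diphosphate, fell from 671 ± 11 to 369 ± 36 TPM, and Fdft1, the squalene synthase, by 0.56 on the log2 scale. Lipogenesis genes were lower for 11 of 17 tested members (12 adjusted over the list alone, camera adjusted p = 2.15e-06, adjusted p = 0.162 with an estimated correlation), among them the fatty acid synthase Fasn (-0.69 ± 0.067) and the desaturase Scd2 (-1.75 ± 0.11). Genes of differentiated hepatocyte function fell as well. Hepatocyte markers were lower for 14 of 17 tested members (14 adjusted over the list alone). Ahsg (fetuin-A) stood at -0.55 ± 0.033 and Trf (transferrin) at -0.44 ± 0.040 (camera adjusted p = 1.59e-11). Of the bile acid genes 7 of 12 (7 adjusted over the list alone) were lower (camera adjusted p = 4.50e-05), with Baat, which conjugates bile acids to amino acids, falling from 30.6 ± 0.74 to 13.7 ± 0.83 TPM and the phospholipid exporter Abcb4 at -0.84 ± 0.080. Of the glucose metabolism genes 6 of 10 (7 adjusted over the list alone) were lower (camera adjusted p = 1.88e-05, adjusted p = 0.0497 with an estimated correlation). The glucose transporter Slc2a2 fell from 97.2 ± 2.8 to 27.9 ± 4.0 TPM.

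Chaperones of the endoplasmic reticulum rose in FLOX cells: Hspa5 (BiP) from 243 ± 3.8 to 455 ± 19 TPM, Hsp90b1 by 0.93 ± 0.047 and Pdia4 by 0.99 ± 0.048. Of the unfolded protein response list 12 of 20 tested members (13 adjusted over the list alone) were higher and 4 lower (camera adjusted p = 0.0306, adjusted p = 0.468 with an estimated correlation). That set result was lost without FLOX palmitic acid replicate 1 (camera adjusted p = 0.107) and with a filter of 5 TPM (0.0579). Genes of p53 signalling and apoptosis were higher for 13 of 22 tested members (14 adjusted over the list alone, camera adjusted p = 0.00464, adjusted p = 0.235 with an estimated correlation). Btg2, an antiproliferative gene, stood at 0.59 ± 0.052 and Phlda3, an inhibitor of Akt, at 0.64 ± 0.077. Genes of extracellular vesicle biogenesis were higher for 9 of 14 tested members (10 adjusted over the list alone, camera adjusted p = 7.55e-04, adjusted p = 0.162 with an estimated correlation). The small GTPase Rab31 stood at 0.92 ± 0.068 and the tetraspanin Cd63 at 0.33 ± 0.029, while the tetraspanin Cd81 stood at -0.36 ± 0.035. Acute phase genes were lower for 7 of 20 tested members (8 adjusted over the list alone) and higher for 4 (4 over the list alone, camera adjusted p = 0.0112, adjusted p = 0.235 with an estimated correlation). The fibrinogen chain Fgb stood at -0.54 ± 0.033. Quantile normalization took that set to an adjusted p of 0.0521.

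Sphingolipid genes moved in both directions. In the sphingomyelin turnover list 3 of 9 were higher and 4 lower (3 and 4 adjusted over the list alone, camera adjusted p = 0.337), with Smpd2, another neutral sphingomyelinase, at -0.47 ± 0.092. In the ceramide metabolism list 8 of 23 were higher and 1 lower (8 and 2 adjusted over the list alone, camera adjusted p = 0.337), with Sphk1, which makes sphingosine-1-phosphate, at 1.18 ± 0.13 and Ugcg, the glucosylceramide synthase, at 0.66 ± 0.10. In the inflammatory signalling list 5 of 15 were higher and 5 lower (5 and 6 adjusted over the list alone, camera adjusted p = 0.337), where the chemokine Ccl2 fell from 310.3 ± 9.7 to 155 ± 19 TPM and the NF-κB subunit Nfkb2 rose by 0.33 ± 0.051. In the interferon list 5 of 18 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.192). The interferon-induced Oasl1 stood at 0.53 ± 0.077 and Cxcl10 at 0.93 ± 0.20. Without FLOX palmitic acid replicate 1 the interferon list passed the threshold (camera adjusted p = 0.0279). In the NRF2 and oxidative stress list 5 of 19 were higher and 7 lower (5 and 7 adjusted over the list alone, camera adjusted p = 0.127). The autophagy receptor Sqstm1 stood at 0.53 ± 0.038 and the glutathione transferase Gstm1 at -0.58 ± 0.032. In the caveolae list 2 of 7 were higher and 2 lower (2 and 3 adjusted over the list alone, camera adjusted p = 0.388), in the cell cycle list 1 of 9 were higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.442), and in the list of mitochondrially encoded genes 1 of 13 were higher and 1 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.293).

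In all, 4084 of 11858 tested genes changed with palmitic acid in FLOX cells, 2726 higher and 1358 lower, and 209 of them by at least 1 on the log2 scale (limma adjusted p below the threshold of 0.05). Large changes outside the lists were the rises of Hmga2, a chromatin protein of growing cells (2.23 ± 0.12), and Erfe, the hormone erythroferrone (2.36 ± 0.12), and the falls of Bex3 (-2.97 ± 0.15), Psca (-2.63 ± 0.11) and the adrenergic receptor Adra1b (-2.23 ± 0.14). The median log2 fold change of all tested genes was 0.096, and the share of changed genes that were higher was 66.7%, against 45.4% with median-ratio scaling, 50.4% with quantile normalization and 51.2% after a correction for transcript length and GC content chosen after the data were seen. Each of these settings centres the samples on a common level, which alone brings the share near 50%, so these shares do not speak on transcript length. In the other alternatives the share ran from 62.7% (without FLOX vehicle replicate 3) to 74.6% (without both FLOX libraries numbered 1). When genes were ranked by transcript length into 4 equal bins, the median of the longest bin lay 0.12 above that of the shortest in FLOX and 0.099 above it in HKO. Per sample this gap was 0.085 in FLOX vehicle replicate 1 against -0.20 to -0.12 in the other 3 of its group and -0.22 in FLOX palmitic acid replicate 1 against 0.059 to 0.14 in its group.

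In HKO cells palmitic acid raised Plin2 from 400.0 ± 14 to 2356 ± 131 TPM, Cidec by 1.81 ± 0.070 and Pdk4 from 0.960 ± 0.16 to 26.9 ± 3.6 TPM. Cholesterol biosynthesis genes were lower for 18 of 22 tested members (19 adjusted over the list alone, camera adjusted p = 1.39e-16, adjusted p = 0.0454 with an estimated correlation). Fdps fell from 756 ± 15 to 388 ± 19.6 TPM. Lipogenesis genes were lower for 12 of 17 tested members (12 adjusted over the list alone, camera adjusted p = 5.20e-08, adjusted p = 0.122 with an estimated correlation). Scd1 stood at -0.87 ± 0.082. Hepatocyte markers were lower for 13 of 17 tested members (14 adjusted over the list alone) and higher for 1 (1 over the list alone, camera adjusted p = 5.73e-09), and bile acid genes lower for 6 of 12 tested members (6 adjusted over the list alone, camera adjusted p = 1.10e-04). Glucose metabolism genes were lower for 5 of 10 tested members (5 adjusted over the list alone) and higher for 2 (2 over the list alone, camera adjusted p = 6.30e-04, adjusted p = 0.122 with an estimated correlation). Fatty acid uptake genes were lower for 6 of 14 tested members (7 adjusted over the list alone) and higher for 3 (3 over the list alone, camera adjusted p = 0.0239, adjusted p = 0.158 with an estimated correlation). Cd36 stood at -0.74 ± 0.10. Of the fatty acid oxidation list 13 of 25 (13 adjusted over the list alone) were higher and 5 lower, and the set missed the threshold (camera adjusted p = 0.0631) but passed it with no filter on TPM (0.00140), with quantile normalization (0.0459) and without HKO vehicle replicate 4 (0.0347) or HKO palmitic acid replicate 2 (0.0476).

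Of the unfolded protein response list 15 of 20 (16 adjusted over the list alone) were higher with palmitic acid in HKO cells and 3 lower (camera adjusted p = 5.18e-05, adjusted p = 0.149 with an estimated correlation). Hspa5 rose from 233 ± 11 to 559 ± 23 TPM and Hsp90b1 by 1.36 ± 0.047. The inducible cytosolic chaperones Hspa1a and Hspa1b, near-identical copies whose reads the counting could have split between them, rose from 2.09 ± 0.50 to 29.9 ± 6.6 TPM and from 8.78 ± 0.49 to 68.8 ± 14 TPM. Genes of p53 signalling and apoptosis were higher for 15 of 22 tested members (18 adjusted over the list alone, camera adjusted p = 6.30e-04, adjusted p = 0.149 with an estimated correlation). The growth arrest gene Gadd45a stood at 0.92 ± 0.078. Vesicle biogenesis genes were higher for 12 of 14 tested members (12 adjusted over the list alone, camera adjusted p = 6.30e-04, adjusted p = 0.134 with an estimated correlation). The tetraspanin Cd9 stood at 0.53 ± 0.047. Acute phase genes were lower for 10 of 20 tested members (10 adjusted over the list alone) and higher for 2 (2 over the list alone, camera adjusted p = 6.30e-04, adjusted p = 0.134 with an estimated correlation). Itih4 stood at -0.45 ± 0.040. Mitochondrially encoded genes were lower as a set (camera adjusted p = 0.0147, adjusted p = 0.346 with an estimated correlation), a result lost with quantile normalization (0.648), and 2 of 13 (2 adjusted over the list alone) were lower. The camera adjusted p of the lipid droplet, sphingomyelin, ceramide, inflammatory, interferon, NRF2, caveolae and cell cycle lists ran from 0.255 to 0.984.

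In HKO cells 5040 genes changed, 3491 higher and 1549 lower (limma adjusted p below 0.05), and 273 by at least 1 on the log2 scale. The share higher was 69.3%, against 47.0% with median-ratio scaling, 51.9% with quantile normalization and 52.4% after the length and GC correction. Both genotypes shared 2241 higher genes, where independent lists of these sizes would share 803, and 1124 lower genes, where they would share 177. These comparisons have no library in common. Across the 11858 genes, which are not independent replicates, the log2 fold changes of the genotypes correlated at r = 0.734 (Spearman rho = 0.752), with a slope of 0.80 of HKO on FLOX.

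**Figure D2:**
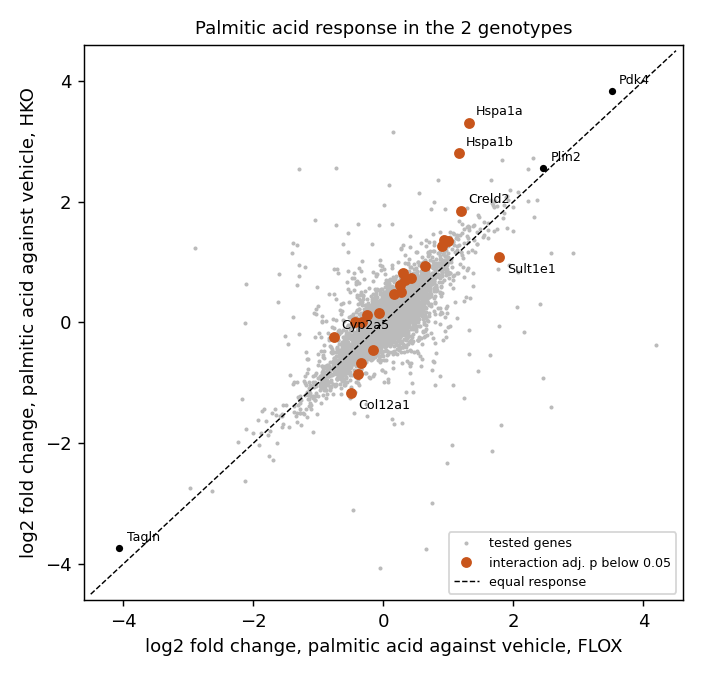
Log2 fold change of each tested gene with palmitic acid in FLOX (x axis) and HKO cells (y axis), with the 23 genes whose response differed between genotypes in orange and the line of equal response dashed. Most genes lie along the line (r = 0.734 across genes), while Hspa1a and Hspa1b lie above it and Sult1e1 below it.

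With vehicle, the acute phase list was higher in HKO cells. Haptoglobin, Hp, was 1384 ± 28 TPM in FLOX and 2206 ± 23 TPM in HKO cells, and hemopexin, Hpx, 2923 ± 56 and 4523 ± 52 TPM. Of the acute phase list 14 of 20 (15 adjusted over the list alone) were higher in HKO and 0 lower, with a median log2 difference of 0.29 (camera adjusted p = 2.78e-17, and 0.00323 with an estimated correlation). Cyp2e1, a cytochrome P450 of ethanol and drug metabolism, was 155 ± 2.4 TPM in FLOX and 58.8 ± 2.5 TPM in HKO cells, Cyp2a5 93.6 ± 4.3 and 23.9 ± 1.5 TPM, and Cyp3a11 differed by -0.90 ± 0.068, while Cyp1a1, another cytochrome P450, was 5.79 ± 0.68 and 15.5 ± 1.0 TPM. Fatty acid oxidation genes were lower for 9 of 25 tested members (12 adjusted over the list alone, camera adjusted p = 3.31e-04, adjusted p = 0.247 with an estimated correlation). The thiolase Acaa1b stood at -0.88 ± 0.068, the fatty acid hydroxylase Cyp4a10 at -0.64 ± 0.062 and Angptl4 at -0.73 ± 0.052.

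Proliferation genes were lower in HKO for 6 of 9 tested members (6 adjusted over the list alone, camera adjusted p = 4.42e-04, adjusted p = 0.171 with an estimated correlation). The ribonucleotide reductase subunit Rrm2 stood at -0.48 ± 0.067 and Pcna, the replication clamp, at -0.27 ± 0.043. NRF2 and oxidative stress genes were lower for 6 of 19 tested members (7 adjusted over the list alone, camera adjusted p = 0.0139, adjusted p = 0.247 with an estimated correlation). The quinone reductase Nqo1 stood at -0.47 ± 0.061 and Gstm1 at -0.35 ± 0.032. That set result was lost with median-ratio scaling (0.127). Glucose metabolism genes were higher for 2 of 10 tested members (2 adjusted over the list alone) and lower for 1 (1 over the list alone, camera adjusted p = 0.0331, adjusted p = 0.291 with an estimated correlation). Igfbp1, an insulin-repressed binding protein, rose from 324 ± 14 in FLOX to 485 ± 12 TPM in HKO. The set missed the threshold without FLOX vehicle replicate 3 (0.0552) or FLOX palmitic acid replicate 3 (0.0526). Hepatocyte markers split: 6 of 17 were higher and 5 lower (7 and 5 adjusted over the list alone, camera adjusted p = 0.453). Single members of other lists differed: the fatty acid binding proteins Fabp1 and Fabp4 by -0.50 ± 0.060 and -0.43 ± 0.063, the ceramide desaturase Degs1 by -0.33 ± 0.043, the desaturase Scd2 by 1.00 ± 0.11, the lipid droplet gene Fitm1 by -1.08 ± 0.11, the bile acid receptor Nr1h4 by -0.45 ± 0.070 and the caveolar protein Cavin1 by 0.89 ± 0.074. No other list fixed in advance passed as a set (camera adjusted p from 0.0909 to 0.852), but the caveolae list did without FLOX vehicle replicate 4 (0.0375) and the interferon list without HKO vehicle replicate 4 (0.0414).

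Outside the lists, HKO cells with vehicle had more Moxd1, a monooxygenase (0.360 ± 0.050 TPM in FLOX and 6.24 ± 0.45 in HKO), Slc16a3, a lactate transporter (2.07 ± 0.33), Pfkp, a glycolytic kinase (1.65 ± 0.18), Ndufa4l2 (1.39 ± 0.27) and the secreted hepatokine Fgl1 (92.1 ± 3.0 and 218 ± 7.7 TPM). They had less Hsd3b1, a steroid dehydrogenase (5.62 ± 0.51 and 0.465 ± 0.22 TPM), the methyltransferase Inmt (-1.58 ± 0.10) and the trefoil peptide Tff1 (-1.42 ± 0.15). In all 1384 genes differed, 487 higher and 897 lower in HKO, 49 of them by at least 1 on the log2 scale (limma adjusted p below 0.05). The share higher was 35.2%, against 56.6% with median-ratio scaling, 51.9% with quantile normalization and 47.1% after the length and GC correction, settings that each centre the samples.

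Under palmitic acid the acute phase list was again higher in HKO cells, and so was the unfolded protein response list. Of that list 13 of 20 (15 adjusted over the list alone) were higher and 0 lower in HKO, with a median log2 difference of 0.31 (camera adjusted p = 2.55e-15, and 0.0219 with an estimated correlation), where with vehicle 1 was higher. Hspa5 was 455 ± 19 TPM in FLOX and 559 ± 23 TPM in HKO cells, and Herpud1, a part of endoplasmic reticulum-associated degradation, 91.7 ± 1.9 and 119 ± 3.8 TPM. Herpud1 was the member already higher in HKO with vehicle, by 0.21 on the log2 scale. Its mean TPM was lower with palmitic acid than with vehicle in both genotypes. Hspa1a and Hspa1b were higher in HKO by 2.07 ± 0.19 and 1.80 ± 0.15. Acute phase genes were higher for 12 of 20 tested members (13 adjusted over the list alone) and lower for 1 (1 over the list alone, camera adjusted p = 6.36e-13, and 0.0124 with an estimated correlation). Hp stood at 0.54 ± 0.032 and Hpx at 0.64 ± 0.036. Inflammatory genes were higher for 4 of 15 tested members (5 adjusted over the list alone, camera adjusted p = 6.54e-04, adjusted p = 0.206 with an estimated correlation). Ccl2 stood at 155 ± 19 TPM in FLOX and 267 ± 53 TPM in HKO and the adhesion molecule Icam1 differed by 0.63 ± 0.10.

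Lower in HKO under palmitic acid were fatty acid oxidation genes for 6 of 25 tested members (8 adjusted over the list alone, camera adjusted p = 1.03e-06, adjusted p = 0.0763 with an estimated correlation). Cyp4a14 stood at -1.02 ± 0.087. Fatty acid uptake genes were lower for 5 of 14 tested members (6 adjusted over the list alone) and higher for 1 (2 over the list alone, camera adjusted p = 0.00624, adjusted p = 0.117 with an estimated correlation). Fabp1 stood at 748 ± 43 TPM in FLOX and 488 ± 44 TPM in HKO and Fabp4 differed by -0.64 ± 0.063. Cell cycle genes were lower for 5 of 9 tested members (7 adjusted over the list alone, camera adjusted p = 1.16e-05, and 0.0439 with an estimated correlation), and cholesterol biosynthesis genes for 4 of 22 tested members (8 adjusted over the list alone, camera adjusted p = 8.58e-04, adjusted p = 0.337 with an estimated correlation). The kinase Pmvk stood at -0.30 ± 0.059. Bile acid genes were lower for 5 of 12 tested members (6 adjusted over the list alone) and higher for 1 (1 over the list alone, camera adjusted p = 0.0331, adjusted p = 0.0940 with an estimated correlation). Cyp27a1, a sterol hydroxylase, stood at -0.26 ± 0.046. The bile acid set result was lost without FLOX palmitic acid replicate 1 (0.0613) or HKO palmitic acid replicate 2 (0.0895). Of the NRF2 list 3 of 19 were higher and 7 lower (3 and 7 adjusted over the list alone, camera adjusted p = 0.0802), and the set passed without FLOX palmitic acid replicate 1 (0.0367) or HKO palmitic acid replicate 4 (0.0200). Hepatocyte markers split again: 7 of 17 were higher and 5 lower (7 and 7 adjusted over the list alone, camera adjusted p = 0.752). No other list fixed in advance passed as a set (camera adjusted p from 0.113 to 0.992), but the mitochondrial list did, lower in HKO, without FLOX palmitic acid replicate 1 (0.0271). Scd1 was 353 ± 45 TPM in FLOX and 232 ± 12 TPM in HKO cells.

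In all 1155 genes differed between genotypes under palmitic acid, 503 higher and 652 lower in HKO, 43 of them by at least 1 on the log2 scale (limma adjusted p below 0.05), against 669 with these 2 groups alone in the fit. The share higher was 43.5%, against 55.0% with median-ratio scaling, which centres the samples. The genotype differences with vehicle and with palmitic acid, which share no library, had 292 higher genes in common, where independent lists would share 20.7, and 370 lower genes, where they would share 49.3. Across genes they correlated at r = 0.424 (Spearman rho = 0.478).

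**Figure D3:**
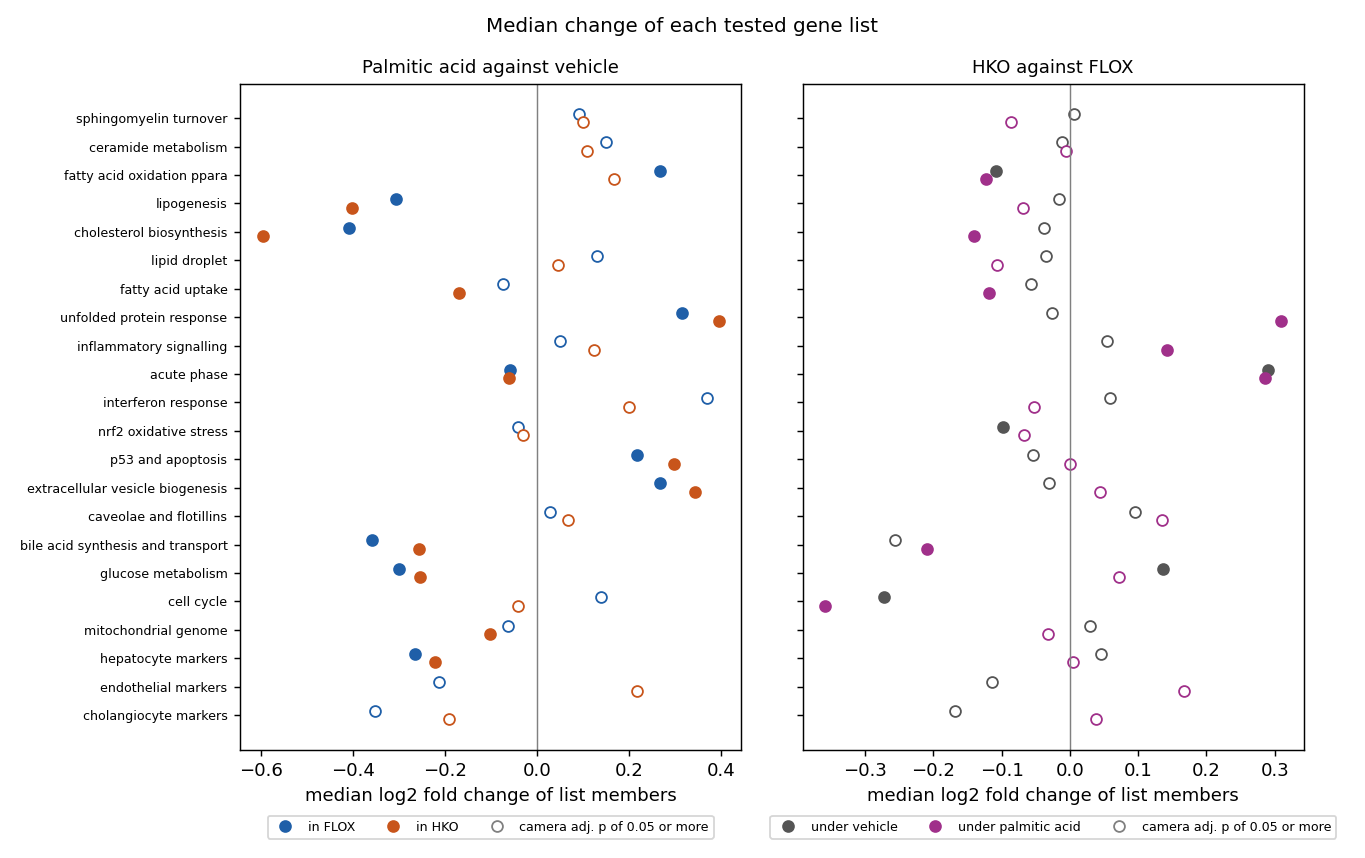
Median log2 fold change of each gene list (y axis) in the comparisons of palmitic acid with vehicle and of HKO with FLOX (x axis, log2 scale), with filled marks for lists past the threshold of 0.05 in the camera test. Cholesterol biosynthesis stood at -0.41 with palmitic acid in FLOX, acute phase genes at 0.29 in HKO with vehicle and the unfolded protein response at 0.31 in HKO with palmitic acid.

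Of the genes whose response differed between the genotypes, the chaperones Hspa1a and Hspa1b had the largest differences. Hspa1a rose by 1.32 in FLOX and 3.31 in HKO cells on the log2 scale, a difference of 1.99 ± 0.27, and Hspa1b by 1.16 and 2.81, a difference of 1.65 ± 0.21. Creld2, Hsp90b1, Hspa5 and Pdia4, which fold proteins in the endoplasmic reticulum, rose more in HKO by 0.66 ± 0.10, 0.43 ± 0.066, 0.36 ± 0.056 and 0.36 ± 0.068. Of the unfolded protein response list 5 of 20 members responded more in HKO and none less, 13 adjusted over the list alone, with a median difference of 0.24 (camera adjusted p = 1.56e-19, and 0.0175 with an estimated correlation). Hmox1, the heme oxygenase, fell with palmitic acid in FLOX (-0.44) and stood at 0.00056 in HKO, and Igfbp1 did likewise (-0.32 and 0.0028). Cyp2a5 fell less in HKO, by a difference of 0.53 ± 0.077, and Ifrd1 and Cyp2c29 differed by 0.52 ± 0.091 and 0.37 ± 0.065. Responses lower in HKO were those of Sult1e1, an estrogen sulfotransferase, which rose from 5.29 ± 0.33 to 20.7 ± 0.97 TPM in FLOX and from 4.96 ± 0.33 to 11.7 ± 1.2 TPM in HKO, of the collagen Col12a1 (-0.66 ± 0.11), of Gckr (-0.46 ± 0.085), of Tmem37, a membrane protein (-0.32 ± 0.059), and of Fah, an enzyme of tyrosine breakdown (-0.30 ± 0.053). Of 27 alternatives, all with the same sign, Hspa1a passed in 27, Creld2 passed in 26, Hsp90b1 passed in 25, Hspa5 passed in 23, while Hmox1 passed in 14, Col12a1 in 13, Gckr, Fah and Cyp2c29 in 10 each and Ifrd1 in 8. Pdia4 (limma adjusted p = 0.0497) passed in 4, and leaving out any 1 of the 16 libraries ended its call, with the highest adjusted p, 0.135, without FLOX palmitic acid replicate 3. Tmem37 passed in 7, and any 1 of 14 libraries ended its call, with the highest adjusted p, 0.103, without FLOX vehicle replicate 2. Leaving out FLOX vehicle replicate 1 alone ended the calls of Hmox1, Col12a1, Gckr, Fah, Cyp2c29 and Ifrd1 (limma adjusted p = 0.0672 for Col12a1 and 0.0728 for the other 5).

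**Figure D4:**
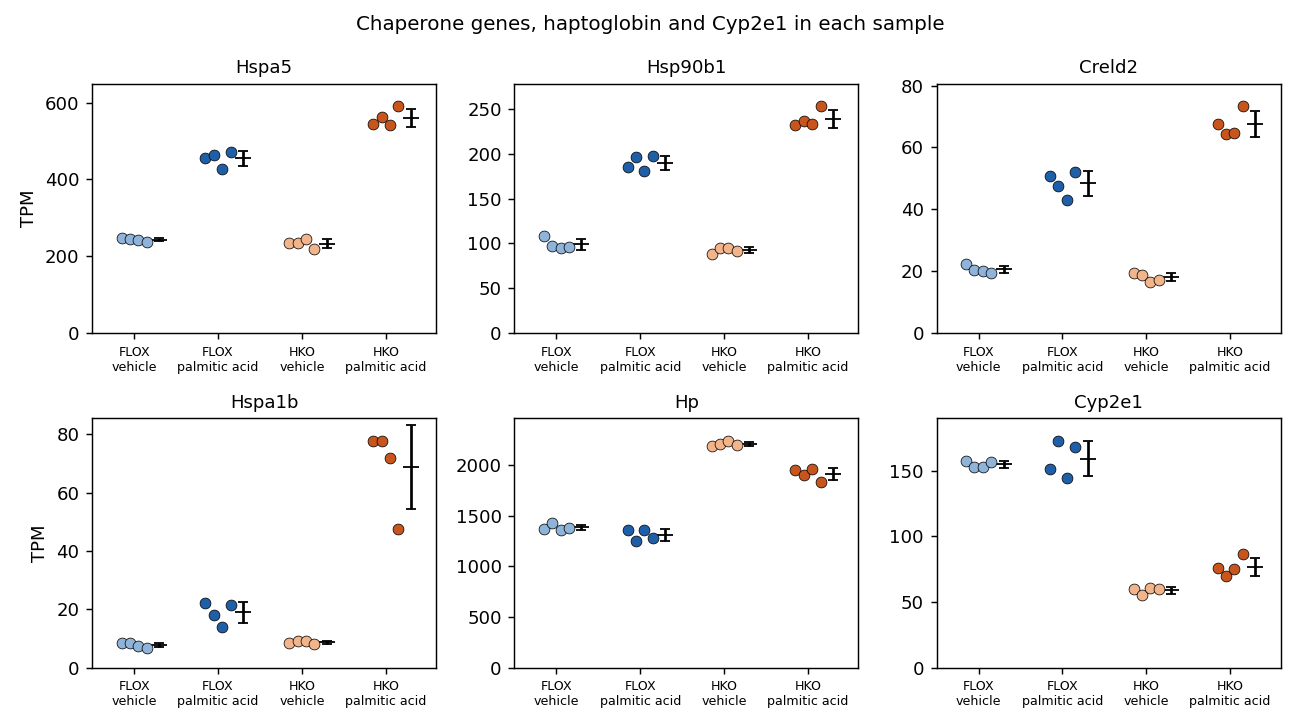
TPM (y axes, linear) of Hspa5, Hsp90b1, Creld2, Hspa1b, Hp and Cyp2e1 in each sample (points) of the 4 groups, with the mean and SD of each group. Hspa5 reached 455 TPM in FLOX and 559 TPM in HKO cells with palmitic acid, and Hspa1b in HKO palmitic acid replicate 4, at 47.6 TPM, lay below the other 3 of its group.

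Among all tested genes 23 responded differently in the genotypes, 18 with a higher response in HKO than in FLOX and 5 with a lower one (limma adjusted p below 0.05), and 893 had an unadjusted p below 0.05, where 593 would by chance. Of 9 with median-ratio scaling 5 were higher and 4 lower, of 31 after the correction for length and GC content 17 and 14, and of 20 without both FLOX libraries numbered 1, 10 and 10. The count was 3 with the replicate block, 5 without the mean-variance trend and 40 with sample quality weights. Leaving out 1 library took it to between 8 and 24. It was 8 without FLOX vehicle replicate 1 or HKO vehicle replicate 2, and 12 of the 16 libraries moved it by more than 1.5 times, the exceptions being FLOX palmitic acid replicates 1 and 2, HKO vehicle replicate 4 and HKO palmitic acid replicate 4. Of the other lists, the cholesterol (median -0.13, camera adjusted p = 1.82e-05), lipogenesis (-0.095, 0.00184), fatty acid uptake (-0.10, 0.0316) and mitochondrial (-0.092, 0.0179) lists responded lower in HKO and the inflammatory (0.17, 0.0179) and p53 (0.064, 0.0337) lists higher. All 6 had an adjusted p = 0.548 with an estimated correlation, and their members past the threshold adjusted over the list alone numbered 0, 2, 1, 1, 0 and 1. The responses of all other tested lists fixed in advance were not shown to differ (camera adjusted p from 0.183 to 0.981). The interferon list passed, lower in HKO, without FLOX palmitic acid replicate 1 (0.00291), HKO vehicle replicate 4 (0.0143) or HKO palmitic acid replicate 4 (0.0396), and the acute phase list without the last of these (0.0230). The lower response of the mitochondrial list was lost without any of 6 libraries (up to 0.108 without HKO vehicle replicate 1) and that of fatty acid uptake without any of 5 (up to 0.130 without HKO palmitic acid replicate 2). The higher response of the p53 list was lost without any of 9 (up to 0.138 without FLOX palmitic acid replicate 1), and that of the inflammatory list without HKO palmitic acid replicate 2 (0.0744).

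Whether the loss of Smpd3 moved the genes that palmitic acid changed in FLOX cells back or further was read from the sign of the genotype difference under palmitic acid. Of those 4084 genes 55.8% had the opposite sign, with a jackknife SE of 8.9 points from leaving out each library. The FLOX palmitic acid libraries enter both comparisons, and simulations with no genotype effect gave 58.7% (57.3 to 60.0% in 50 simulations). With these libraries divided so that no library entered both, the share was 47.6% on average over 6 divisions, from 37.2% to 42.6% where FLOX palmitic acid replicate 1 was in the genotype difference and from 53.8% to 56.6% where it was in the response. The covariance of the fold changes was -0.0155 against -0.0157 in the simulations, a difference of 0.000247. Over the 6 divisions it was 0.0035 on average, from -0.0048 to 0.0142, a spread far wider than that difference. The simulations drew noise for each gene on its own and so hold no structure that genes of a library share. No general return toward vehicle levels was therefore measured in HKO cells, but with this spread between divisions a shift either way is not excluded.

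Of the listed markers of macrophages, stellate cells, endothelial cells, lymphocytes and neutrophils most were not tested. Of 15 macrophage markers 1 was tested, the lysosomal protein Cd68, which palmitic acid raised by 0.50 ± 0.084 in HKO and 0.33 ± 0.084 in FLOX cells (limma adjusted p = 1.95e-04 and 0.00714, the latter 0.0517 with median-ratio scaling) and which stood higher in HKO by 0.47 ± 0.084 under palmitic acid (limma adjusted p = 0.00184). With vehicle it stood higher by 0.29 ± 0.084 (limma adjusted p = 0.0336), a call lost with no filter on TPM (0.0812) and without any 1 of 7 of the 8 vehicle libraries, all but FLOX vehicle replicate 4, with the highest adjusted p, 0.105, without HKO vehicle replicate 3. No lymphocyte or neutrophil marker was tested. Of 12 stellate cell and fibroblast markers 2 were tested: Tagln, an actin-binding protein, fell with palmitic acid from 56.5 ± 3.9 to 2.48 ± 0.58 TPM in FLOX and from 96.8 ± 6.7 to 6.50 ± 1.9 TPM in HKO cells, and Timp1, named after its values were seen, rose by 0.47 ± 0.14 and 0.58 ± 0.14. Of 9 cholangiocyte markers 5 were tested, with a summed level of 199 ± 4.5, 220 ± 20, 321 ± 12 and 377 ± 22 TPM in FLOX vehicle, FLOX palmitic acid, HKO vehicle and HKO palmitic acid samples. Of these 2 rose and 3 fell with palmitic acid in FLOX (camera adjusted p = 0.126) and 2 and 2 in HKO (0.255). Krt7 stood at -1.38 ± 0.10 and Krt19 at -0.67 ± 0.12 in FLOX. Spp1 (osteopontin) was 149 ± 6.0 TPM in FLOX and 274 ± 12 TPM in HKO cells with vehicle, and the cholangiocyte list did not differ between genotypes as a set (camera adjusted p = 0.628 with vehicle and 0.199 with palmitic acid). Of 12 endothelial markers 4 were tested, and 1, Stab2, was higher in HKO with vehicle (0.55 ± 0.12), and the list did not pass in any comparison (camera adjusted p = 0.337, 0.830, 0.628, 0.167 and 0.528). Neither of the 2 tested erythroid markers changed past the threshold in any comparison. Mitochondrially encoded transcripts made up 9.15 ± 0.16, 8.89 ± 0.76, 9.03 ± 0.19 and 8.57 ± 0.22% of TPM in FLOX vehicle, FLOX palmitic acid, HKO vehicle and HKO palmitic acid samples, and the 20 most abundant genes 27.2 ± 0.22, 25.3 ± 0.24, 28.1 ± 0.36 and 25.9 ± 0.063%.

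The median, the mean and the set test of a list differed in sign in 26 of the tests of lists fixed in advance, all but 3 of them in the comparisons of single factors and none past the threshold. With palmitic acid they were those of the sphingomyelin, inflammatory, NRF2 and caveolae lists in both genotypes, of the cell cycle and mitochondrial lists in FLOX and of the endothelial list in HKO. Between genotypes they were those of the ceramide and hepatocyte lists under both treatments, of the sphingomyelin, lipogenesis, cholesterol, unfolded protein response, vesicle, endothelial and cholangiocyte lists with vehicle and of the interferon list with palmitic acid. In the interaction they were the NRF2, caveolae and glucose lists. Of the 7 lists chosen later the pericentral list with palmitic acid in FLOX, the actin and SRF list between genotypes with vehicle and the periportal list in the interaction did so too, none past the threshold.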

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

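The tests of a single deviating library, of separate preparations, of read sharing, of heat shock genes, of FLOX palmitic acid replicate 1, of composition, of fatty acid uptake and of transcript length were chosen after the results they address were seen.

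The response to palmitic acid differed between the genotypes for 18 of the genes named here, by the interaction test. It was higher in HKO for Hspa1a (1.99), Hspa1b (1.65), Creld2 (0.66), Cyp2a5 (0.53), Ifrd1 (0.52), Hmox1 (0.44), Hsp90b1 (0.43), Cyp2c29 (0.37), Hspa5 (0.36), Pdia4 (0.36), Igfbp1 (0.33), Dnajb1 (0.31) and Hspa8 (0.23, all log2). It was lower for Sult1e1 (-0.70), Col12a1 (-0.66), Gckr (-0.46), Tmem37 (-0.32) and Fah (-0.30). Of the lists, the unfolded protein response (0.24), inflammatory (0.17) and p53 (0.064) lists had higher median responses in HKO, and the lipogenesis (-0.095), cholesterol (-0.13), fatty acid uptake (-0.10) and mitochondrial (-0.092) lists lower ones. With an estimated correlation the camera adjusted p was 0.0175 for the unfolded protein response list and 0.548 for each of the others.

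The larger chaperone response of HKO cells was weighed against technical causes. Read sharing between Hspa1a and Hspa1b would leave their sum alone, but the summed TPM, 9.79 and 25.3 in FLOX and 10.9 and 98.6 in HKO with vehicle and palmitic acid, responded more in HKO by 1.78 ± 0.22. Without FLOX palmitic acid replicate 1 the unfolded protein response list kept its interaction (camera adjusted p = 7.37e-17), and with median-ratio scaling too (camera adjusted p = 9.28e-17), over a range of 8.08e-24 to 0.0175. Whether more fatty acid reached the HKO cells stays open, since oxidation and lipid droplet genes went both ways in the interaction (larger median -0.030, standard deviations over members 0.18 and 0.21). Loss of Smpd3 stays open too. It cannot be told apart from the Cre recombinase, which only HKO cells carry, or from separate preparations of the genotypes (highest correlation 0.112).

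The genotype difference shared by both treatments was weighed next. DNA of another strain around Smpd3 stays open: its 100 tested neighbours held 1.36% of the shared calls (9 of 661) but were too few to hold most of them, and 9% of the neighbours were called against 5.55% of other genes (Fisher's exact two-sided p = 0.127). Nnt, which is truncated in C57BL/6J, differed by 0.21 ± 0.088 and 0.043 ± 0.088. Its mean level was 4.78 TPM, and the TPM of a whole gene may not show the truncation. A difference of substrain therefore stays open. At least 981 genes differed under vehicle whichever library was left out. Separate preparations of the genotypes cannot be told apart from the genotype, since FLOX and HKO samples of the same number correlated at 0.112 at most and no label ties them. Loss of Smpd3 stays open beside them and cannot be told apart from the Cre recombinase, which only HKO cells carry. Hypoxia target genes were part of this difference (smaller median 0.27), as described under the other observations. Whether loss of Smpd3 acts through them was not tested.

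Palmitic acid raised more genes than it lowered in TPM, and composition may account for part of this. The 200 most abundant genes fell from 59.7% to 58.1% of TPM in FLOX and from 60.5% to 58.6% in HKO, which raises all others by 0.054 and 0.067 on the log2 scale. A trend with transcript length was open: the longest genes exceeded the shortest by 0.12 in FLOX and 0.099 in HKO. No biological explanation was tested.

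Other splits of the samples were counted. For palmitic acid in FLOX (4084 genes) and in HKO (5040), and for HKO against FLOX under vehicle (1384) and under palmitic acid (1155), 1 of 35 splits, the real one, gave as many genes, and the highest others gave 2635, 1, 2 and 25. For the interaction (23 genes) it was 1 of 100, and the highest other gave 2. Chance was thus made unlikely for each but not excluded. A share of 1 in 35 or 1 in 100 is the smallest that these splits can give. The libraries may be technical replicates, so the splits do not speak for separate preparations. The split with 2635 genes set FLOX vehicle replicate 1 with FLOX palmitic acid replicates 2, 3 and 4, which points to a structure of the samples: FLOX vehicle replicate 1 and FLOX palmitic acid replicate 1 had length gaps of 0.085 and -0.22, PC3 scores of 16.1 and -19.0, and quality weights of 0.49 and 0.30. Without both, 5268 genes changed with palmitic acid in FLOX.

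Of 464 tests for a sample far from the other 3 of its group 26 were met, where chance gives about 23.2 at 1 in 20. FLOX palmitic acid replicate 1 did so for Fdft1 (65.5 TPM, others 59.4 to 60.4), Rab31 (52.8 TPM, others 63.2 to 64.5), Relb (11.2 TPM, others 10.1 to 10.2), Cyp3a11 (192 TPM, others 246 to 255), Cd68 (55.1 TPM, others 66.1 to 67.8) and genes above 0 TPM (17733, others 18241 to 18345). FLOX vehicle replicate 2 did so for Adra1b (19.3 TPM, others 22.1 to 22.5), Fasn (99.7 TPM, others 93.2 to 93.9), Pmvk (101 TPM, others 95.7 to 96.1) and Fabp4 (186 TPM, others 196 to 198). HKO palmitic acid replicate 4 did so for Erfe (13.9 TPM, others 11.7 to 11.9), Hspa1b (47.6 TPM, others 72.0 to 77.7) and Akr1c14 (6.59 TPM, others 8.92 to 9.23). HKO vehicle replicate 1 did so for Cidec (26.4 TPM, others 33.6 to 34.5) and Pcna (79.2 TPM, others 76.7 to 76.8). FLOX palmitic acid replicate 3 did so for Cd36 (4.64 TPM, others 3.53 to 3.70) and Inmt (19.9 TPM, others 24.6 to 25.4). HKO vehicle replicate 3 did so for Hsd17b13 (263 TPM, others 244.93 to 247) and Cd68 (68.0 TPM, others 60.1 to 61.2). HKO vehicle replicate 4 did so for Fdps (777 TPM, others 746 to 750.4). FLOX vehicle replicate 4 did so for Fgb (681 TPM, others 668 to 669.9). HKO palmitic acid replicate 1 did so for Itih4 (350.3 TPM, others 326 to 328). FLOX vehicle replicate 1 did so for Ndufa4l2 (4.58 TPM, others 6.26 to 6.63). HKO vehicle replicate 2 did so for Cyp2e1 (55.2 TPM, others 59.6 to 60.6). FLOX palmitic acid replicate 4 did so for mt-Co2 (588 TPM, others 709 to 718). HKO palmitic acid replicate 3 did so for Cyp2c29 (31.5 TPM, others 31.9 to 32.0).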

How the results depend on the processing

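The correction for length and GC content, protein-coding genes alone and leaving out both FLOX libraries numbered 1 were chosen after the data were seen. Of 237 results for named genes 207 kept their side of the threshold, and their direction where past it, in every alternative run for them. Of the 30 others 15 were in the interaction. A change of sign between values that both missed the threshold was not counted. The Smpd3 interaction, for example, kept its sign in 22 of 27 alternatives. Not all were run for each: the filter of 5 TPM covered 223, protein-coding genes 235 and 2 groups in the fit 218. Of 110 list results 70 kept theirs. Of 41 list calls 29 were lost with an estimated correlation. No result past the threshold in the main fit or the alternative reversed.

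The genes that differed under palmitic acid numbered 669, against 1155, with 2 groups in the fit. The same fit gave 1258 against 1384 between genotypes under vehicle. With palmitic acid it gave 3397 against 4084 in FLOX and 5076 against 5040 in HKO. Fewer samples set the spread in each, so that alone does not account for the fall, and its cause was not tested. The interaction, 23 genes, had 9 with median-ratio scaling, 5 without the mean-variance trend, 40 with quality weights and 8 to 24 with 1 library left out; the cause was not tested. It needs all 4 groups, so the fit with 2 was not run. With the replicate block the interaction had 3 genes, and palmitic acid changed 3191 genes in FLOX, against 4084, and 4231 in HKO, against 5040. The sample titles give vehicle and palmitic acid samples of a genotype the same numbers, so these may share a source. Same-number correlations ran from -0.15 to 0.11, and in 5 of 16 comparisons a sample matched its own number best. With 4 samples per group such correlations cannot settle whether the samples are paired. The agreement of the responses, 0.734, was 0.619 with a pseudocount of 0.1, 0.634 with no filter and 0.706 to 0.738 with 1 library left out. The opposite share, 55.8%, ran from 53.7% to 64.4% with 1 library left out. TPM hold no depth, so its limit is unknown.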

Other observations

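The tests of the heat shock genes and of fatty acid uptake, and the choice of all 7 lists here, came after the main results were seen. These lists were tested in the same libraries that gave those results, so none of the tests is independent of them. The hypoxia test was set before its result.

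HKO cells had less of the genes that hepatocytes near the central vein express and more of secreted plasma proteins. Pericentral genes were lower for 10 of 12 with vehicle and 7 of 12 with palmitic acid, with medians of -0.52 and -0.36 (camera adjusted p = 1.83e-04 and 9.82e-04 with an estimated correlation). Complement and coagulation genes were higher for 16 of 23 and 14 of 23 (0.29 and 0.23, camera adjusted p = 0.00222 and 0.00935 with an estimated correlation), and lower with palmitic acid for 16 of 23 in FLOX and 19 of 23 in HKO. Periportal genes were higher in HKO for 7 of 12 and 6 of 12, with 2 lower in each (camera adjusted p = 0.0286 and 0.0701 with an estimated correlation) and lower with palmitic acid for 9 of 12 and 8 of 12. Proteasome genes were lower in HKO for 21 of 31 and 12 of 31 (camera adjusted p = 1.83e-04 and 9.82e-04 with an estimated correlation). With palmitic acid they were higher for 15 of 31 and 22 of 31, but with median-ratio scaling the camera adjusted p was 0.487 and 0.202. Actin and SRF target genes were lower with palmitic acid for 10 of 15 and 9 of 15 (camera adjusted p = 0.0277 and 0.0671 with an estimated correlation). In the interaction the pericentral (0.15, camera adjusted p = 0.00158) and proteasome (0.026, 0.0270) lists responded higher in HKO and the hypoxia (-0.063, 0.0147) and complement (-0.039, 0.0270) lists lower, with no member past the threshold, and all 4 were lost with an estimated correlation (0.101, 0.199, 0.443 and 0.443).

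A hypoxia-type response was a hypothesis drawn from Slc16a3, Pfkp and Ndufa4l2, and tested in the same libraries on 21 hypoxia targets outside the named genes. They were higher in HKO for 14 of 21 with vehicle and 11 of 21 with palmitic acid, with medians of 0.39 and 0.27 (camera adjusted p = 0.00489 and 0.0142 with an estimated correlation). Angptl4 and Hilpda, named genes that hypoxia can also raise, did not enter this list and did not follow it. With vehicle Angptl4 was 122 ± 7.7 TPM in FLOX and 73.2 ± 4.3 TPM in HKO, and Hilpda 11.3 ± 1.0 and 11.5 ± 1.8 TPM. Culture density or oxygen may differ between the preparations, so the hypoxia-type response could be technical or due to Smpd3 or Cre (smaller median 0.27).

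A general heat shock response in HKO was tested on 16 further heat shock genes. Left out were 4 that had passed in the interaction: Hspa1a, Hspa1b, Hspa8 (0.23, limma adjusted p = 0.0344) and Dnajb1 (0.31, limma adjusted p = 0.0394). Hspa8 passed in 8 of 27 alternatives and was lost without any 1 of 12 libraries (up to 0.0912 without FLOX palmitic acid replicate 3), and Dnajb1 passed in 6 and was lost without any 1 of 15 (up to 0.109 without HKO palmitic acid replicate 1). For the 16 genes the interaction median was 0.074 (camera adjusted p = 0.0595), and 0.443 with an estimated correlation. None was higher in HKO past the threshold: 4 were lower with vehicle and 2 with palmitic acid, with medians of -0.14 and -0.077 (camera adjusted p = 9.09e-04 and 0.125, and 0.122 and 0.493 with an estimated correlation). Whether these 16 respond more to palmitic acid in HKO stays open. The test of summed Hspa1a and Hspa1b was set after this result was seen.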
